A study of Prunus mume with 13 samples.

How the data were processed

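Total RNA of vegetative buds was labelled with Cy3 and hybridised to 1-colour Agilent arrays, per the labels' protocols. There were 13 samples. Each of the 10 field months was 1 array, and each of the 3 chilling times was 3 arrays, which the series' design text calls biological replicates, so there were 19 arrays on 6 slides. The labels do not say from which trees or branches the replicates came, so p-values measure the spread between these arrays.

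The deposited scanner files hold spot intensities on a linear scale. Per the file headers they were made with Feature Extraction 10.7.1.1, which subtracts background, corrects spatial trends and gives dim spots a surrogate value, with no scaling between arrays. Each probe was printed in 3 spots on an array with few exceptions, and these are technical. One 0 d array (replicate 2) carried the scanner software's quality result "evaluate", and the others "in range". A deposited value table holds log2 values made by the authors, 1 column per sample, per the design text as means of spots and, for chilling, of arrays. How it was normalized is not given in the sources used here. Its differences between samples followed those computed here with slopes from 0.99 to 1.03 and a correlation across probes of at least 0.994. Its columns have a mean of 0 and medians of -0.07 (June), -0.07 (July), -0.05 (August), -0.06 (September), -0.003 (October), 0.05 (November), 0.02 (December), -0.01 (January), -0.04 (February), 0.04 (March), 0.03 (0 d), 0.02 (40 d) and -0.05 (60 d). Scale and direction follow from that comparison, and the level to which probes were centred stays unknown. It served only as an alternative for single probes.

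From the deposited intensities the log2 of the processed signal was averaged over a probe's spots, leaving out control spots and spots flagged as outliers, and the array's 75th percentile was subtracted. A probe was called well above background on an array when the majority of its spots were. It entered the chilling tests when this held on every array of at least 1 time (56891 probes) and the seasonal tests when it held on at least 2 months (57542 probes). Where a probe was not well above background on any array of a group, the change is given as "at least N-fold": the mean of the brighter group against the mean, per array, of the higher of the probe's own value and the lowest value among probes well above background.

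Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with Benjamini-Hochberg adjustment and a threshold of 0.05. The 3 chilling times were fitted together (6 residual degrees of freedom). The 10 months were grouped by the stage label, so that months of a stage serve as its samples and change between months counts as spread (4 residual degrees of freedom). Chilling replicates were compared first, and no 2 arrays held identical values. Arrays differed by slide: June to September, October to January, and February with March each filled a slide; 0 d shared a slide with 1 array of 60 d, the other 60 d arrays were on another, and 40 d had its own.

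The fits were tested on simulated data made from the real means and spreads with 200 changed probes. For 60 d against 0 d (56891 probes) the fit recovered 35.8% of 1.5-fold, 74.6% of 2-fold and 93.9% of 4-fold changes, with 6 false calls. For ecodormant against endodormant months (57542 probes) it recovered none of the 1.5-fold (0%) or 2-fold (0%) and 37.9% of the 4-fold changes, with 0 false calls. The simulated noise was independent between probes and held no slide effect, and fewer probes changed than were called in the data. These shares and false calls need not carry over to the real fits.

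The array's names for its probes are contig, read and peach model names. None of them (0) matched the RefSeq gene table of assembly ASM2933915v1, so gene names were not used, and the gene lists fixed before the data were examined could not be tested. The rule for named probes, fixed at the same time, was then the 2 largest fitted increases and 2 largest fitted decreases per comparison among probes past the threshold whose groups do not overlap. Chance gives 10% of probes without overlap for 3 against 3 arrays. For 2 against 3 months, as in the stage comparisons, that share is larger. For 15 contigs with 2 probes, the log2 changes from 0 to 60 d of the 2 probes differed by a median of 0.03 and at most 0.19, with the same sign in 13.

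Alternatives fixed before the data were examined were quantile normalization, normexp background correction (offset 50), other filters on dim probes, a mean-variance trend, a 2-fold minimum, slide and replicate letter as blocks, the median of spots, fits of only 2 groups, and leaving out each array. The files held the median and not the mean spot signal, so normexp used the median signal and the median local background. Cyclic loess between the chilling arrays, scaling on the median of all probes or on spike-in probes, February alone as the ecodormant month, the joint fit of all arrays, and all groupings of probes by time course were chosen after seeing the data. Spike-in probes are Agilent's added control transcripts: 6 of the 10 were used, those well above background on all arrays without the brightest. On that scale an error in an array's spike-in level shifts all its probes together, while the tests treat probes as separate. Counts of calls on that scale therefore show how directions depend on the scale, and not how many probes changed.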

Results

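Gene expression was measured in vegetative buds of Japanese apricot (Prunus mume, cultivar Nanko), a stone fruit tree whose buds stop growing in summer and need winter cold before they can grow out again. The data formed 2 sets. In the chilling set, cut branches collected in November were stripped of leaves and kept for 0, 40 or 60 days (d) in a chamber at 12 °C for 9 h of light and 6 °C for 15 h of dark, with 3 arrays for each time. No sample came from branches kept as long without cold. Chilling below therefore means time in that chamber, and cold cannot be told apart from time since cutting, leaf removal or the light given. In the seasonal set, field buds were sampled once a month from June to March, with 1 array for each of the 10 months. The labels gave each sample a dormancy stage. June buds were paradormant (held back by the shoot tip), July and August buds facultatively endodormant, September buds endodormant with the word facultative in brackets, and buds of October to December and of 0 d endodormant, that is, held back by the bud itself. Buds of January and 40 d were labelled between endodormant and ecodormant, and buds of February, March and 60 d ecodormant, that is, held back only by outside conditions.

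Each array carried 58642 probes, and between 95.8% and 97.4% of them were well above background on each of the 19 arrays. The 75th percentile of the signal ranged from 3821 to 8848 scanner units, and no probe was saturated. Replicate arrays of a chilling time agreed closely, with a Spearman rho across probes of 0.989 to 0.996. The median SD between the 3 arrays was 0.11 on the log2 scale at 0 d, 0.12 at 40 d and 0.14 at 60 d. The probes stand for assembled contigs (20203 probes), single sequencing reads (38351 probes) and peach gene models (88 probes). The files used here did not pair these with gene names, so the groups described are groups of probes defined by their response, and single probes are given by their identifier. Several probes may report the same transcript, so all counts are of probes and not of genes. The number of arrays limits the precision, and 1 array per month allows no replicate check within a month.

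Expression in the buds changed broadly during chilling. Of 56891 probes tested over the 3 times, 44662 (78.5%) differed in the limma moderated F test at an adjusted p below 0.05, and 14127 of these differed at least 2-fold between some pair of times. At least 2-fold changes were called for 7612 probes between 0 and 40 d, 8625 between 0 and 60 d and 7440 between 40 and 60 d. Replicate arrays of one time, by comparison, differed at least 2-fold in 175 to 501 of the 54786 probes that were well above background on all 19 arrays.

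**Figure D1:**
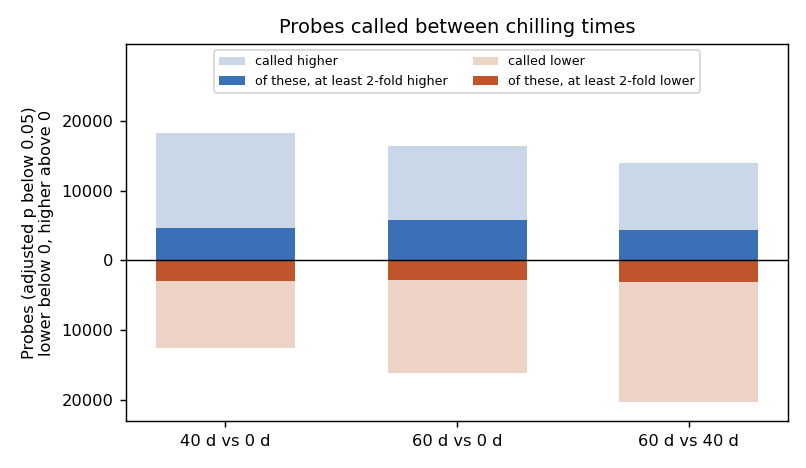
Number of probes (vertical axis) called higher or lower at an adjusted p below 0.05 in each of the 3 comparisons of chilling times (horizontal axis), with those that changed at least 2-fold in the darker shade. At least 2-fold increases outnumbered at least 2-fold decreases in each comparison, with 5779 against 2846 probes between 0 and 60 d; on the spike-in scale 40 against 0 d turned to 2529 higher and 6511 lower.

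The comparison of 60 d with 0 d covers the passage from endodormant to ecodormant buds under controlled cold. Among the strongest changes, 5779 probes were at least 2-fold higher and 2846 at least 2-fold lower at 60 d, and 308 rose and 227 fell at least 10-fold. Probe Ume57949 was not well above background on any 0 d array and was at least 332-fold higher at 60 d, where its normalized log2 signal was 0.21 ± 0.13 (SD, n = 3; limma adjusted p = 5.3e-07). It lay at -5.47 ± 1.14 (SD, n = 3) at 40 d. Probe Ume31635 went from -7.04 ± 1.12 at 0 d, where 2 of 3 arrays measured it above background, through -1.94 ± 0.64 at 40 d to 2.22 ± 0.20 at 60 d (SD, n = 3 each; limma adjusted p = 7.07e-07). In the other direction, Ume36298 fell from 1.78 ± 0.23 at 0 d to -4.95 ± 0.19 at 40 d, and at 60 d it was not well above background, at least 1155-fold lower than at 0 d (SD, n = 3; limma adjusted p = 2.86e-10). Ume24887 fell by 10.18 on the log2 scale, from 2.36 ± 0.17 to -7.83 ± 0.21, with 2 of 3 arrays at 60 d well above background (SD, n = 3; limma adjusted p = 2.86e-10). With normexp background correction all 4 kept their direction and call with smaller changes, 56.6-fold and 160.5-fold higher for Ume57949 and Ume31635 and 306.1-fold and 273.5-fold lower for Ume36298 and Ume24887. The bounds therefore hold for the processed signal only. With normexp 4279 probes were called at least 2-fold higher and 2429 at least 2-fold lower at 60 d. In all, 32585 probes (57.3%) passed the test, 16439 higher and 16146 lower at 60 d. One 60 d array shared its slide with the 3 arrays of 0 d. With slide as a block 24639 probes were called, and within the shared slide alone 24111; both rest on that 1 array of 60 d, assumed to vary like the other arrays in the fit. Scaling on spike-in probes in place of the 75th percentile turned the split to 18732 higher and 1378 lower and moved the median of all probes from -0.02 to 0.59 on the log2 scale, so all directions here are relative to the 75th percentile of each array. The counts on the spike-in scale do not give the number of probes that changed, because an error in an array's spike-in level shifts all its probes.

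**Figure D2:**
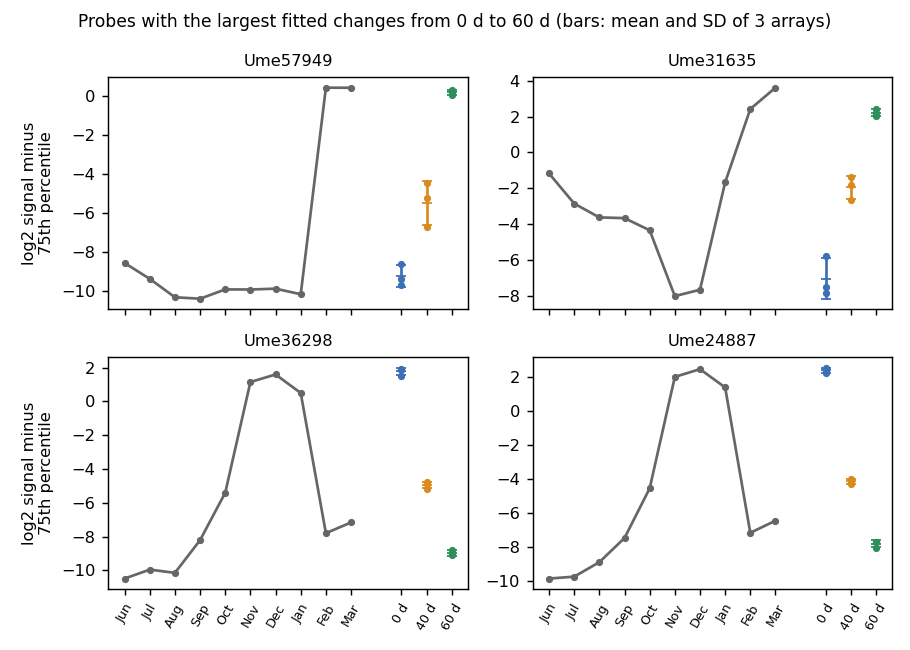
Normalized log2 signal (vertical axes, log2 signal minus the array's 75th percentile) of the 4 probes with the largest fitted changes between 0 and 60 d, in the 10 field months (grey, 1 array each) and at 0, 40 and 60 d of chilling (points, 3 arrays each, with bars for mean and SD). The 2 upper probes were highest in February, March and at 60 d, and the 2 lower probes were highest in November to January and at 0 d.

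Many probes differed already at 40 d. At least 2-fold, 4697 probes were higher and 2915 lower than at 0 d. With normexp background correction these counts were 3246 and 2353. Ume28148 was not well above background at 0 d and was at least 103-fold higher at 40 d, at -1.48 ± 1.097 (SD, n = 3; limma adjusted p = 7.48e-07), and Ume29080 rose from -6.56 ± 0.62 to 1.35 ± 1.23 (SD, n = 3; limma adjusted p = 3.83e-06). Both stood higher at 60 d than at 0 d too, at -1.98 ± 0.24 and -0.69 ± 0.52 (SD, n = 3). Ume58152 and Ume21419 did not keep their change: they were not well above background at 40 d, at least 162-fold and at least 114-fold lower than at 0 d (limma adjusted p = 2.59e-06 and 2.49e-06, n = 3), and at 60 d they were back at -1.69 ± 0.59 and -2.13 ± 0.53 (SD, n = 3), a level the test did not separate from 0 d (limma adjusted p = 0.15 and 0.164). With normexp the changes to 40 d were 18.7-fold and 82.2-fold upward for Ume28148 and Ume29080 and 30.5-fold and 27.0-fold downward for Ume58152 and Ume21419. The test called 30771 probes, 18254 higher and 12517 lower. The balance of the 2 directions depended on the scaling: with the median of all probes as the scale it was 14874 higher and 15743 lower, and with the spike-in probes 2903 higher and 8062 lower, where the median of all probes moved from 0.08 to -0.33 on the log2 scale. The 40 d arrays filled 1 slide of their own, so slide and chilling time cannot be told apart in any comparison with 40 d.

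Between 40 and 60 d, 4288 probes rose and 3152 fell at least 2-fold. With normexp background correction these counts were 3377 and 2325. Ume58152 and Ume21419, which had dropped by 40 d, rose again and were now at least 81.6-fold and at least 60.1-fold higher (limma adjusted p = 1.16e-05 and 1.1e-05, n = 3). Ume18824 and Ume28797 fell from -2.60 ± 0.09 and -2.73 ± 0.19 (SD, n = 3) to levels not well above background, at least 54.0-fold and at least 51.0-fold lower (limma adjusted p = 3.86e-06 and 1.97e-06). With normexp the rises of Ume58152 and Ume21419 were 15.4-fold and 14.3-fold, and the falls of Ume18824 and Ume28797 were 10.73-fold and 12.47-fold. The test called 34159 probes, 13886 higher and 20273 lower. With the spike-in probes as scale the split was 35384 higher and 500 lower, and the median of all probes moved from -0.10 to 0.91 on the log2 scale. The spike-in level itself varied between arrays of a time, with an SD of 0.28 at 40 d and 0.55 at 60 d (n = 3). An error in an array's level shifts all its probes together, so the counts on this scale may mostly repeat that shift. The limma adjusted p of Ume58152 became 1.45e-121 on this scale, too small to be taken at face value from 9 arrays.

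The 2 steps together sorted the probes into time courses. A steady rise, called in both steps, was seen in 2358 probes, with median log2 changes of 0.74 and 0.72, and a steady fall in 1913 probes, with medians of -0.60 and -0.56. More probes turned back: 9971 rose to 40 d and fell again to 60 d, and 6146 fell and then rose, 16117 in all. Of the probes that rose and fell, 57.7% were not called between 60 and 0 d, and of those that fell and rose, 55.2% were not. Turning back at least 2-fold in both steps was seen in 1171 probes that rose first and 1267 that fell first. A further 5925 probes were called as rising and 4458 as falling in the first step with no call in the second, and 5382 rising and 8389 falling in the second with no call in the first; whether the 2 steps differed was not tested for these. The steps share the 40 d arrays, which by itself favours opposite signs. If the 2 lists of calls were independent, 9560 probes would turn back. The covariance of the 2 steps across probes was -0.204, against -0.013 in 20 simulated sets with unchanged groups. Those sets had a mean of 0 probes that turned back. Noise of the shared arrays, as simulated, was thus small against the observed covariance. The correlation was -0.347, against -0.501. In unchanged groups it follows from the shared arrays whatever the size of the noise, so it does not measure their part. An offset common to the 40 d arrays was not simulated. With the median of all probes as scale, the probes that turned back split into 7852 rising first and 7685 falling first, with cyclic loess normalization into 7640 and 7708, and with the spike-in probes into 193 and 6679.

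The changes from 0 to 40 d and from 0 to 60 d overlapped in direction. Both comparisons called 9401 probes higher and 6567 lower, where independent lists of these sizes would share 5275 and 3552, and 3567 probes were called in opposite directions, against 8797. Both rest on the same 0 d arrays. The covariance of the 2 sets of log2 changes was 0.416, against 0.013 in simulated unchanged groups, and the correlation across probes was 0.603, against 0.499. Noise of the shared arrays, as simulated, was thus small against the observed covariance. The correlation in unchanged groups follows from the shared arrays whatever the size of the noise, so it does not measure their part. An offset common to the 0 d arrays was not simulated and may add to the overlap. These arrays were too few to divide.

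In the field, the month-to-month change was largest at the end of the series. From February to March 9987 of the 55163 probes that were well above background in all 10 months differed at least 2-fold, 3583 higher and 6404 lower. The next largest steps were January to February (5561 probes, 3284 higher), September to October (5143 probes, 3091 lower) and October to November (4931 probes, 3633 lower). The smallest were July to August (2418 probes) and November to December (2559 probes). The January to February and the September to October steps also crossed slides, while the February to March step lay within 1 slide. Of the 15812 probes with at least a 4-fold range over the year, 24.7% were highest and 35.8% lowest in March, and 1.4% were highest in October. These counts describe single arrays and have no test.

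The comparison of ecodormant with endodormant field buds set February and March against October, November and December. At least 2-fold, 1025 probes were higher and 1240 lower in the ecodormant months. Ume57949, named above for its rise between 0 and 60 d, was not well above background in any endodormant month either and was at least 359-fold higher in February and March, at 0.43 ± 0.003 (SD, n = 2; limma adjusted p = 9.13e-04). Ume24114, well above background in 1 of the 3 endodormant months, rose from -7.34 ± 2.25 (SD, n = 3) to 2.73 ± 0.47 (SD, n = 2; limma adjusted p = 0.0206). Ume07240 and Ume31394 were at 2.41 ± 2.42 and 2.48 ± 2.48 (SD, n = 3) in the endodormant months and not well above background in the ecodormant ones, at least 2064-fold and at least 2175-fold lower (limma adjusted p = 0.0191 and 0.02). They stood at 3.66 and 3.75 in October, 3.95 and 4.07 in November, and -0.38 and -0.37 in December. These 2 probes ran in parallel over all arrays, as did Ume36298 with Ume24887, Ume58152 with Ume21419, and Ume18824 with Ume28797. Whether the probes of such a pair report the same transcript was not checked. With normexp the changes were 93.4-fold and 271.2-fold upward for Ume57949 and Ume24114 and 311.2-fold and 316.7-fold downward for Ume07240 and Ume31394. Ume57949 kept its call without October, without November and without December, and it was not tested without February or without March. The calls of Ume24114, Ume07240 and Ume31394 were lost without single months while the fitted log2 changes stayed close to those of all months (10.07, -12.12 and -12.01): they were 9.59, -11.35 and -11.22 without November and 9.73, -11.61 and -11.70 without March. The adjusted p of Ume24114, Ume07240 and Ume31394 was 0.102, 0.0917 and 0.0917 without November and 0.112, 0.107 and 0.109 without March, and that of Ume24114 and Ume31394 was 0.0572 and 0.0517 without July and 0.0573 and 0.0517 without August, months outside this comparison that leave the changes as they were. The test called 2483 of 57542 probes, 1080 higher and 1403 lower, with months of a stage as its samples and 4 residual degrees of freedom, and stage was confounded with slide. The count moved with single months: 312 without July and 312 without August, 983 without October, 53 without November, 702 without December, 10995 without February and 120 without March. With the spike-in probes as scale 44998 probes were higher and 626 lower, and the median of all probes moved from -0.03 to 1.36 on the log2 scale. These counts may mostly repeat a shift common to all probes, because an error in a month's spike-in level enters every probe of its array.

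Entry into endodormancy, October to December against July and August, gave a single call. Ume02148 was lower in the endodormant months, where it was not well above background, at least 6.02-fold below its July and August level of -5.47 ± 0.30 (SD, n = 2; limma adjusted p = 0.0124). At an unadjusted p below 0.05, limma gave 12053 probes. Without October 2186 probes were called, and leaving out July, August, November, December, February or March each gave 0. Over all of these the fitted log2 change of Ume02148 stayed between -4.66 and -4.23, against -4.44 with all months. The call was also lost with normexp background correction, where the change was 2.58-fold (log2 SE 0.156; limma adjusted p = 0.153), less than the bound above. With a mean-variance trend the fitted log2 change stayed at -4.44 while its SE went from 0.186 to 0.325 (limma adjusted p = 0.196). Where probes had to be well above background on every array, Ume02148 was not tested.

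Chilled buds and field buds were then set side by side. Across the 54786 probes well above background on all arrays, each of the 3 arrays of 0 d was nearest to December (mean Spearman rho 0.982), ahead of November (0.973), and each of the 3 arrays of 60 d was nearest to February (0.981). The 40 d arrays were less close to any month: 2 were nearest to December and 1 to February, with mean rho of 0.952 and 0.948, and January, the month with the same stage label, gave 0.945. These are correlations across probes, which are not independent replicates.

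**Figure D3:**
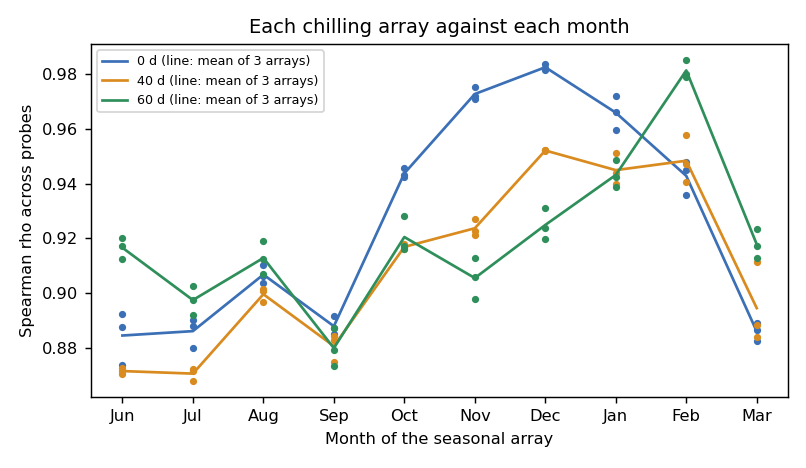
Spearman rho across 54786 probes (vertical axis) between each chilling array and the array of each field month (horizontal axis); points are the 3 arrays of a chilling time and lines their mean. The 0 d arrays peak in December at a mean of 0.982 and the 60 d arrays in February at 0.981.

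Most probes called under chilling had the same sign of change in the field. Of the 32585 probes called between 0 and 60 d, 81.2% had the same sign in the difference of ecodormant and endodormant months, whose arrays were not used for the calls, against 72.7% of all tested probes. Among probes at least 2-fold lower at 60 d, 96.8% were lower in February and March, with a seasonal median of -1.34 against -1.41 under chilling (log2). Among probes at least 2-fold higher at 60 d, 74.7% were higher in February and March, with a seasonal median of 0.91 against 1.57 under chilling. With February alone these shares were 93.7% of the lower and 90.5% of the higher probes, with medians of -1.02 and 1.14. Of the 10 ways to divide the 5 months into 2 and 3, the labelled one gave the highest share (one-sided exact permutation p = 0.1, the smallest that 10 divisions allow), and the next was 71.4%.

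The year-round profile of these probes had its turning point in November and December. The median of the probes that were higher at 60 d was 0.63 relative to their 10-month mean in June, -1.01 in November, 0.53 in February and -0.0045 in March. The probes that were lower at 60 d had a median of -0.35 in June, 0.69 in November and -1.21 in March. In March the first of these medians lay above 83.4% of 10000 random lists of the same size matched on mean signal. The other medians given here lay outside all such lists, which describes these arrays and is not a test across replicates.

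**Figure D4:**
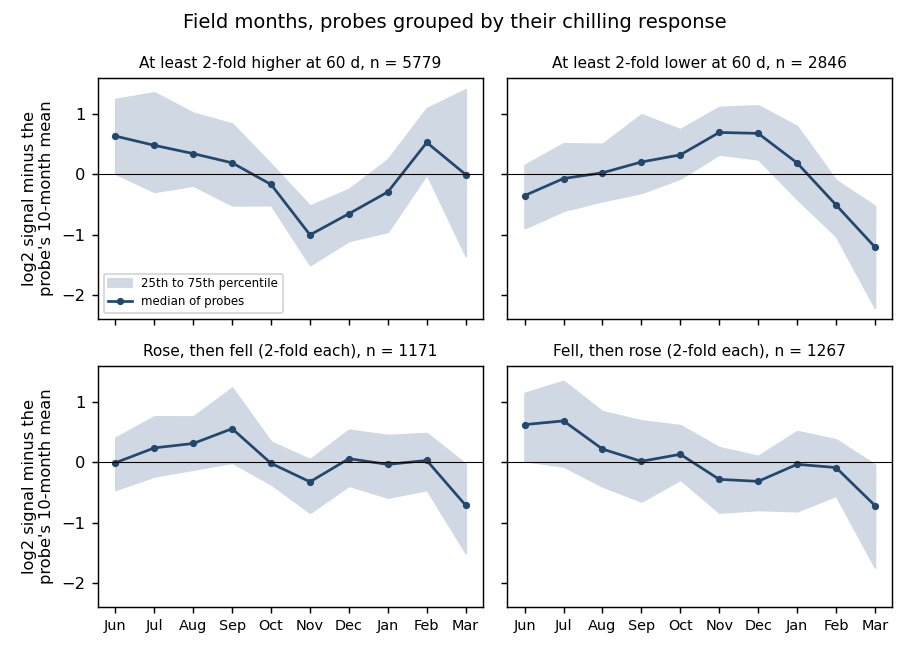
Log2 signal minus each probe's 10-month mean (vertical axes) in the 10 field months (horizontal axes) for 4 groups of probes defined by their chilling response; lines are medians over probes and bands run from the 25th to the 75th percentile. Probes higher at 60 d have their lowest median in November (-1.01), and probes lower at 60 d have their lowest in March (-1.21).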

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

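All tests in this part were chosen, or had their predictions written, after the results were seen.

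The change from 0 to 60 d differed from the change between endodormant and ecodormant months in 1150 of 56870 probes (interaction contrast in a joint limma fit, adjusted p below 0.05). Of these, 1038 changed more in the upward direction under chilling and 112 more in the downward direction, and 648 were called under chilling with the opposite sign in the field. The fit gave each probe a common spread for chilling arrays and months. The median SD was 0.11 at 0 d and 0.14 at 60 d. It was 0.23 over the endodormant months and 0.31 over the ecodormant months. The seasonal change was therefore judged against a spread that may be too small, and the count may be too high. The chilling and field arrays also shared no slide, so the contrast cannot separate slide effects from a difference between chilling and season. The count was 875 with quantile normalization. Single months moved it and the balance of directions: 766 without March, 3186 without December (2191 upward, 995 downward) and 15637 without February (8313 upward, 7324 downward).

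The control transcripts added to the RNA were not among the probes compared and served only as an alternative scale. Their level relative to the 75th percentile ranged over 2.03 log2 units across the months, from 0.64 in September to -1.39 in March. A candidate explanation is that the amount of added transcript or its labelling varied between arrays: the 3 arrays of 60 d alone spanned 1.03 log2 units. A share of messenger RNA set by the bud stage does not alone account for the levels of the chilling and field arrays together. The 0 d arrays lay below the months with the same stage label (difference -1.30 log2, SD 0.29 at 0 d and 0.23 over the months). Chilling and field arrays shared no slide, so an offset between the sets would give this difference too. It therefore cannot decide whether the stage caused the range over the months. The stage stays open as a cause of that range, and slides followed the months.

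The 16117 probes that turned back between 40 and 60 d form the next pattern. A compressed signal range on the 40 d arrays may play a part. The median of the dimmest decile of probes rose by 0.27 to 40 d and then fell by 0.163 (brightest -0.05 and -0.032, all log2). The span of the spike-in probes was 0.19 log2 wider at 40 d than at 0 d. It was not particular to 40 d, with means of 7.85 at 40 d and 7.82 at 60 d (SD 0.04 and 0.08). As the whole cause a compressed range is argued against. Cyclic loess, which removed the shift of the deciles (dimmest 0.029 and 0.007), left 82.7% of the probes turning back. A state that field buds pass through in winter and a state reached only in the chamber both stay open, because each month has 1 array: the deviation of 40 d from the mean of 0 and 60 d had a correlation across probes of -0.056 with the deviation of January from December and February, and of -0.154, 0.253 and -0.068 with the deviations of November, December and February from their neighbouring months. The slide that held only the 40 d arrays cannot be told apart from the chilling time either; arrays of 60 d on different slides differed at least 2-fold in at most 289 probes, while 40 d lay at least 2-fold from the mean of 0 and 60 d in 4624.

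For the count over all 3 chilling times, 1 of 100 splits of the 9 arrays, the real one, gave as many probes (44662, highest other 14630). The 100 were drawn from 280 possible splits, so a count this high is unlikely by chance. The real split nearly follows the slides, so the splits cannot tell chilling time from slide. For the pairs of times, 10 splits are too few for a share under 0.05: in each case 1 split, the real one, had the highest count (30771 for 40 against 0 d, 32585 for 60 against 0 d, 34159 for 60 against 40 d), and the highest other gave 0.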

How the results depend on the processing

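Cyclic loess, the scalings on spike-in probes and on the median of all probes, February alone as the ecodormant month, the joint fit, and the count that turned back were chosen after seeing the data. The chilling counts stayed within 1.5 times under quantile normalization, cyclic loess, normexp, each filter, the trend, the median of spots, and slide as a random block, and those of the 3 pairs of times also with fits of 2 groups. The random block is no check on slide effects, because slide nearly follows chilling time. Its fitted correlation within slides was -0.097, and the counts rose with it. Leaving out each array gave 40526 to 44311 probes over the 3 times, 25557 to 32262 for 40 against 0 d, 27422 to 33291 for 60 against 0 d, 28955 to 33834 for 60 against 40 d, and 12450 to 16086 that turned back. A 2-fold minimum, which by construction keeps fewer probes, left 14127, 7612, 8625, 7440 and 2438 of these. With spike-in probes as scale the counts were 10965 for 40 against 0 d, 20110 for 60 against 0 d, 6872 that turned back, 45624 for ecodormant against endodormant months and 8 for endodormant against facultative months. The cause was not tested, and on that scale an error in an array's spike-in level enters all its probes. Leaving out a month gave 53 to 10995 probes for ecodormant against endodormant, 0 to 2186 for endodormant against facultative, and 766 to 15637 for the difference between chilling and season. Where this left a stage with 1 month, that month is assumed to vary like the others. The single call for endodormant against facultative months was lost (0 calls) with normexp, with the filter on every array and with the trend. The same-sign share was 82.0% for calls of at least 2-fold, 62.5% for calls of 40 against 0 d and 84.7% with February alone. The replicate letters were not taken as pairs, because 2 of the 9 same-letter pairs had deviations correlated below 0.1 (lowest -0.099); the other 7 lay at 0.221 to 0.375, and 8 of 9 arrays correlated best with their own letter, a hint from the data. With the letter as a replicate block the counts were 46603, 33311, 35089 and 36239. No named probe reversed, but with normexp, whose offset lifts dim values, their changes were smaller. The gene list alternatives were not run, because no probe had a gene name. Signal over background limits the dimmest probes, for which changes are bounds.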

Other observations

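Of the tests in this part, the exchange of months was chosen after the result was seen; the others were fixed after the pattern was noticed and before their own values were seen.

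The 1171 probes that rose and then fell at least 2-fold had their highest median in September, 0.56 above the 10-month mean, and their lowest in March (-0.71). The 1267 probes that fell and then rose had their highest medians in June (0.63) and July (0.69) and their lowest in March (-0.72). In January the medians were -0.03 and -0.03, above 70.7% and 11.7% of 10000 random lists matched on mean signal.

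The share of tested probes at least 2-fold higher at 60 d than at 0 d ranged by read-name prefix from 6.58% (MID6) to 14.2% (MID4). It was 9.26% for the 16586 tested probes on plain contigs, 9.11% for the 3161 on contigs with rep in their names and 15.7% for the 115 on contigs with names numbered after an s. The 88 peach gene model probes were dim, with a median normalized log2 signal of -8.49 and 43 of them tested. What the prefixes stand for is not given in the sources used here, and these groups were not tested.

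The 0 d branches were collected in November but were nearer to the December than to the November buds. The labels place the field buds in the middle of each month, while for 0 d only the month is given here. An exchange of the November and December arrays is argued against: neighbouring months were closer as labelled, by 0.0416 in summed Spearman rho (SD between replicate pairs 0.00245). On an axis from September and October to January and February, which uses neither month, 0 d lay at 0.267 ± 0.027 (SD, n = 3), November at 0.046 and December at 0.238. The distance of 0.221 from November, with each 0 d array above it, goes with the hypothesis that the unchilled branches were further along the autumn change. They may have been cut later in November than the field buds, or come from another tree or year, which the labels do not give. An offset of the slide of 0 d cannot be told apart from this hypothesis, since only 1 other array lies on it. That 60 d array differed by 0.0028 on the axis from the 60 d arrays elsewhere.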
